A study of Mus musculus with 2 samples.

How the data were processed

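Anti-FLAG chromatin immunoprecipitation with sequencing was done on mouse LSK cells that carried a FLAG-tagged Hlf virus or a GFP control virus, with 1 library each. Per the labels' protocols, 80000 cells were infected and cultured, chromatin was crosslinked with 1% formaldehyde, and it was sheared in 4 sonication cycles. Bowtie2, bedtools and MACS2, and the build mm10 (GRCm38), are named per the submitters' processing notes, without role or version. The threshold for a peak, any filter, and whether the GFP library served as background are not given in the sources used here.

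The deposited file of the FLAG-HLF library is a list of 3153 intervals with 3 columns (chromosome, start and end) and no header. Every interval is 400 bases wide, so the authors gave the peaks 1 fixed width, by a step that is not given in the sources used here. The list carries no peak height, enrichment or significance, and the order of its lines is not explained. Read depth is therefore unknown, and no detection limit can be given. A peak list for the GFP control library was not analysed here. With a single list there is no spread between replicates.

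Coordinates are given from 1 in mm10. Genes came from a RefSeq table of GRCm38.p6 with 49997 genes, of which 21900 are protein-coding, and all 280 list genes were found in it by symbol. The table gives gene bounds without strand or exons. The planned distances to transcription start sites were therefore replaced by distances from the peak centre to the nearest end of a coding gene, and transcription starts and stops were not told apart. The lower end of a gene is the one with the smaller coordinate. The genome span ran from the first to the last coding gene of each chromosome, 2600 Mb in all, and includes unsequenced gaps. Genome sequence was not used here. The 16 sequence motifs fixed in advance, among them the PAR bZIP site, the scan of short words, the GC matching of random regions and the tests that need a peak score were therefore not run.

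Shares of peaks were tested with the two-sided exact binomial test against the share of the genome span. Clopper-Pearson intervals are at 95%. For the 11 gene lists, 100 random regions per peak were drawn from 400000 positions per chromosome, matched on chromosome and on distance to a coding gene end (bins up to 1, 5, 20, 100 kb and beyond) and not overlapping a peak. In each of 10000 draws 1 region per peak was taken. The two-sided p is 2 times the smaller tail, never under 0.0002, with Benjamini-Hochberg adjustment over the lists. A second test, added after the data were seen, counted list genes with a peak against 10000 random gene lists matched in 10 classes on the chance of a hit. Genes with several peaks were compared with 2000 draws, not the 10000 planned. The counts by chromosome, the share inside genes, the spacing of neighbouring peaks and the exact intervals were added after the data were seen. These tests match gene position, not chromatin accessibility or expression.

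The list test was tested on simulated data for the same 3153 peaks and 21900 genes. In 40 simulated sets without an effect, 13 of 440 list tests (2.95%) had p under 0.05. With 12 peaks planted near the genes of 1 list, the list passed the adjusted threshold in 36 of 40 sets, at a median ratio of 3.66. Real peaks are more clustered than the simulated ones, so these rates do not carry over to the real list. Smaller numbers of planted peaks were not simulated, so recovery of weaker effects is unknown.

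The gene lists, the threshold of 0.05 and most alternatives were chosen before the data were examined. The rule for named genes was also set then. It takes up to 6 genes per list, up to 5 genes with the most peaks, and Hlf, Dbp, Tef and Nfil3. Since the file has no score, genes of a list were ranked by number of peaks and then by the shortest distance to a gene end. A gene of the T and innate lymphoid list that the rule takes is not reported here. The part of the rule on the 20 strongest peaks named none, because all peaks have 1 width. Alternatives changed the distance limit, the gene set, the random regions, the gene assignment and the lines used. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.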

Results

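HLF (hepatic leukemia factor) is a transcription factor of the PAR bZIP family, whose other members include DBP and TEF. Its binding was profiled in mouse hematopoietic stem and progenitor cells of the LSK gate, which lack lineage markers and carry Sca-1 and c-Kit. The cells received a retrovirus with a FLAG-tagged Hlf or a GFP control virus and were cultured for 5 days with SCF, IL-7, Flt3 ligand and IL-3. No marker of the cells after culture was analysed here. Chromatin was then precipitated with an anti-FLAG antibody and sequenced. There was 1 library per arm, so no value below has a replicate check. Only the peak list of the FLAG-HLF library was analysed, and the arms were not compared. Every test below runs across regions or genes of this 1 list, and these are not replicates of the experiment. The list gives positions without read counts, peak heights or significance, so its depth is unknown.

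The FLAG-HLF list held 3153 peaks, each 400 bases wide, covering 1261 kb of the mm10 (GRCm38) genome on the 19 autosomes and X. Most peaks lay away from gene ends but close to genes. Of the 3153 peak centres, 342 lay within 1 kb of either end of a coding gene, 584 at 1 to 5 kb, 926 at 5 to 20 kb, 1028 at 20 to 100 kb and 273 beyond 100 kb. The median distance was 14.0 kb. The 342 peaks at gene ends were 10.8% of the list (95% exact Clopper-Pearson interval 9.78 to 11.98%), against 3.01% of the genome span. This was a 3.60-fold excess (two-sided exact binomial p = 1.07e-89). Within 5 kb the excess was 2.36-fold, with 29.4% of the peaks against 12.4% of the span. Peaks beyond 100 kb of a gene end were 8.66% of the list against 36.5% of the span, a ratio of 0.237 (exact binomial p = 1.92e-286). Coding genes held 1742 peak centres, or 55.2% (53.5 to 57.0%), against 39.6% of the span (exact binomial p = 3.91e-70). Gene ends include both the start and the stop of transcription, since the gene table gives no strand. Exons and introns were not told apart. The intervals cover counting error only.

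**Figure D1:**
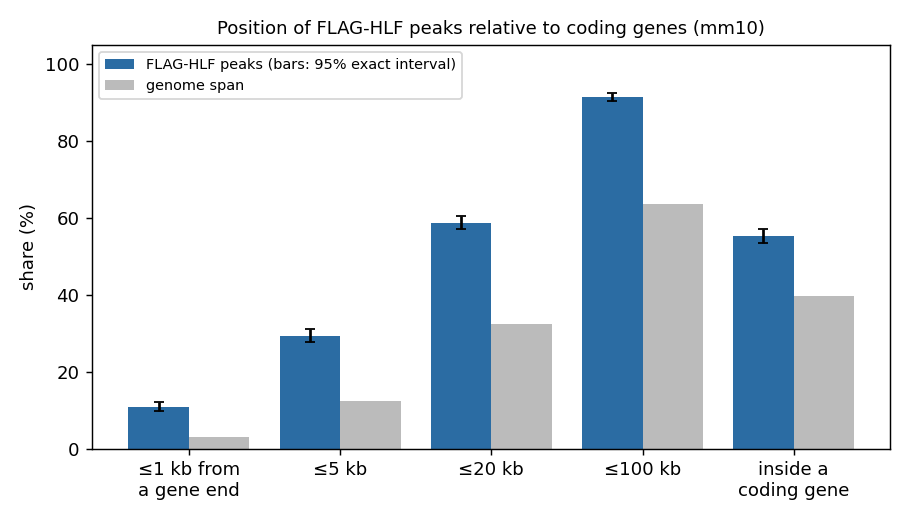
Share of the 3153 FLAG-HLF peak centres (blue) and of the genome span (grey), in percent, within 1, 5, 20 and 100 kb of a coding gene's end and inside a coding gene; error bars are 95% exact intervals over peaks. The peak share was above the genome share in every class drawn, with 10.8% against 3.01% at 1 kb.

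The stated aim was to profile HLF binding across the genome of multipotent progenitors, and 11 gene lists fixed before the data were examined were set against the peaks. Each peak was given to the coding gene with the nearest end within 100 kb. The 273 peaks beyond 100 kb of any gene end were left out of these counts, 114 of them inside a gene. The count per list was compared with 10000 sets of random regions matched on chromosome and distance to a gene end. Of the 280 distinct list genes, 65 had a peak by this rule. There were 4 lists with more peaks than expected, and no list had fewer, at an adjusted p of 0.05 over the 11 lists. They were cytokine signalling, granulocyte and monocyte, clock and PAR bZIP, and B lymphoid genes. Open chromatin of these cells was not matched. The draws took each peak's region on its own, while real peaks gathered at some genes, so these p-values can be too small. With each gene counted once, the cytokine and the granulocyte and monocyte lists passed (permutation adjusted p = 0.0088 and 0.0473). The clock and B lymphoid lists did not (permutation adjusted p = 0.055 and 0.119). The values called permutation p for gene lists came from random draws, not from shuffled labels. The draws took matched regions, or matched genes where random gene lists are named. These p-values are two-sided, apart from those along the lines of the file.

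Cytokine signalling genes showed the highest ratio of the 11 lists. They had 16 peaks against 3.52 ± 1.84 (SD of the random draws) expected, a ratio of 4.55, and 10 of the 25 genes had a peak (permutation adjusted p = 0.0022). Ifngr1, a chain of the interferon gamma receptor (chromosome 10, 19591949 to 19610229), had 5 peaks. The nearest was centred 0.429 kb outside the gene, and the farthest 85.2 kb away. Tgfbr2, a receptor for TGF-beta, had 2 peaks outside the gene, at 0.819 and 2.91 kb from its opposite ends. Cxcr4, the receptor that holds stem cells in the marrow, had 2 at 23.0 and 50.1 kb. Il4ra, a cytokine receptor chain, Stat3, a transcription factor downstream of cytokine receptors, and Tyk2, a kinase bound to such receptors, each had 1 peak inside the gene, at 0.378, 1.22 and 2.40 kb from an end. Counting genes in place of peaks, 40% of the list had a peak against 12.2% of random genes matched on the chance of a hit (permutation adjusted p = 0.011).

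Genes of the circadian clock and the PAR bZIP family had 12 peaks against 4.38 ± 2.10 (SD of draws), a ratio of 2.74, at 9 of 24 genes (permutation adjusted p = 0.011). Peaks lay at an end of Per1 and of Per2, which encode repressors of the clock. Per1 had 1 peak centred 0.285 kb outside its lower end (chromosome 11, 69094624 to 69095023) and another 3.82 kb inside. Per2 had 1 peak 0.093 kb outside its upper end (chromosome 1, 91459245 to 91459644) and another 21.6 kb inside. Tef, the PAR bZIP relative of Hlf, had 1 peak 0.145 kb outside its lower end (chromosome 15, 81802329 to 81802728) and another 7.56 kb inside. Nfil3, a repressor that binds the same DNA site as the PAR bZIP factors, had 1 peak inside (chromosome 13, 52976701 to 52977100). Nr1d2, a nuclear receptor of the clock, had 1 peak 0.487 kb inside its upper end. Bhlhe40, another clock repressor, had 1 peak 1.15 kb outside. Hlf itself had 0 peaks within its bounds (chromosome 11, 90336535 to 90390917), and its closest peak was 95.6 kb away. Dbp had 0 peaks as well, with the closest 81.4 kb away. The call was lost when each gene was counted once against the random regions (ratio 2.34, permutation adjusted p = 0.055). It held against random gene lists (permutation adjusted p = 0.0275). In the first 1576 lines the ratio was 4.27, but the later lines were not tested on their own. Most counted peaks of this list lay in those first lines. The only later ones were the peak at the upper end of Per2 (line 2119) and those of Rora (line 2775) and Nr1d2 (line 2894). The ratio of 4.27 therefore does not show an excess along the whole file.

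The granulocyte and monocyte list had 10 peaks against 3.005 ± 1.72 (SD of draws), a ratio of 3.33, at 8 of 29 genes (permutation adjusted p = 0.011). Id1, an inhibitor of bHLH factors, had 3 peaks within 4.39 kb, 1 of them 0.009 kb inside its lower end (chromosome 2, 152736061 to 152736460). Single peaks lay at Itgam, which encodes CD11b (0.932 kb inside), and outside Prtn3, a granule protease (1.72 kb), Mpo, which encodes myeloperoxidase (3.56 kb), Csf3r, the G-CSF receptor gene (5.58 kb), and Cd33 (8.67 kb). With each gene counted once against the random regions the ratio was 2.87, and the permutation adjusted p of 0.0473 was just under the threshold. Against regions not matched on distance the ratio was 5.09, and against random gene lists 2.82 (permutation adjusted p = 0.0301). In the first 1576 lines it was 5.15, but the later lines were not tested on their own. Most counted peaks of this list lay in those first lines, so the ratio of 5.15 does not show an excess along the whole file.

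B lymphoid genes had 14 peaks against 5.58 ± 2.37 (SD of draws), a ratio of 2.51, at 9 of 27 genes (permutation adjusted p = 0.0115). Syk, a kinase of B cell receptor signalling, had 3 peaks, the nearest 1.51 kb outside its lower end. Flt3, a receptor of early lymphoid progenitors, had 2 peaks inside the gene, 7.64 and 11.4 kb from its upper end. Ikzf3, which encodes Aiolos, had 2 inside, at 12.02 and 16.9 kb. Foxo1, a transcription factor of early B cells, had 2 inside, at 18.1 and 37.5 kb. Blnk, an adaptor of the B cell receptor, had 1 peak 0.099 kb outside its upper end (chromosome 19, 40994121 to 40994520). Pax5, the B cell commitment factor, had 1 peak 6.21 kb inside. The call was lost when each gene was counted once (ratio 1.93, permutation adjusted p = 0.119) and when noncoding genes entered the assignment (ratio 1.52, permutation adjusted p = 0.733). It held against random gene lists (permutation adjusted p = 0.039).

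**Figure D2:**
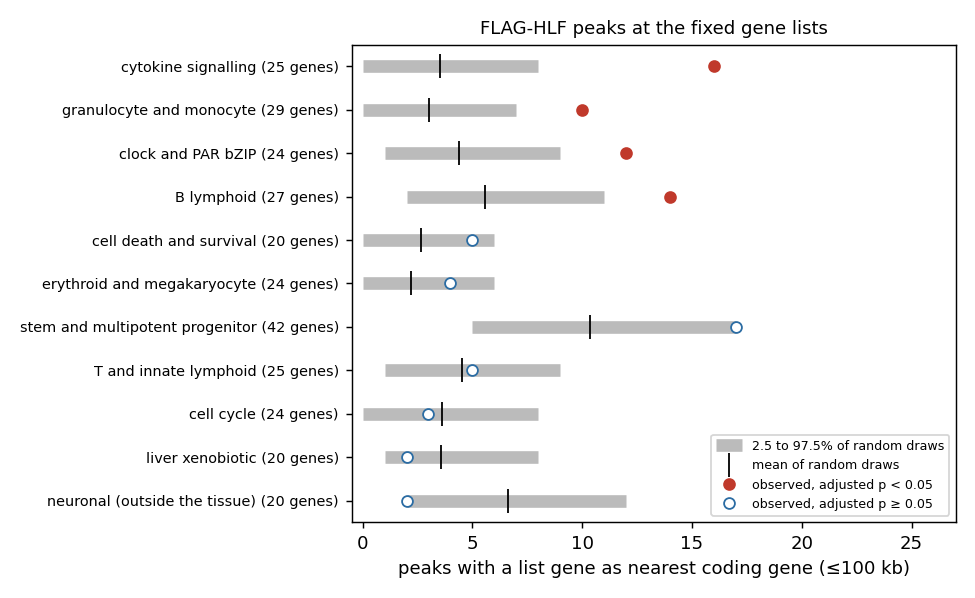
Number of peaks whose nearest coding gene end within 100 kb belongs to each fixed list (circles), with the mean (black ticks) and the central 95% (grey) of 10000 sets of matched random regions; filled red circles have an adjusted p under 0.05. Cytokine signalling had 16 peaks against 3.52 expected, and the neuronal list had 2 against 6.63.

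The other 7 lists did not pass the test. The stem and multipotent progenitor list had 17 peaks at 12 of 42 genes, against 10.3 ± 3.24 (SD of draws) expected, a ratio of 1.64 (permutation adjusted p = 0.138). Against random gene lists, the 28.6% of its genes with a peak compared with 14.5% (permutation adjusted p = 0.0532). Lmo2, a cofactor needed for blood formation, had 3 peaks outside the gene, at 10.8, 11.97 and 51.0 kb from its lower end. Etv6, an ETS factor, had 3 peaks inside, the nearest 37.4 kb from an end. Nkx2-3 had 2, Meis1 had 1 centred 0.654 kb inside its upper end (chromosome 11, 19018798 to 19019197), Egr1 had 1 at 5.75 kb, and Runx1 had 1 at 6.46 kb inside. Another peak inside Runx1 (chromosome 16, 92715432 to 92715831) was 110.4 kb from an end and was not counted. For the lists of T and innate lymphoid, cell death, erythroid, cell cycle and liver genes the permutation adjusted p ran from 0.387 to 1. The T and innate lymphoid list had 5 peaks against 4.52, among them 2 in Zbtb16, 1 in Notch1 and 1 lying 54.3 kb outside Gata3. Cell death and survival genes had 5 against 2.64. Of these, Bmf, a pro-apoptotic gene, had 3 within 6.30 kb, and Bcl2 and Bcl2l11 had 1 each, lying 20.4 and 53.0 kb outside the gene. The peak given to Bcl2l11 lay inside another coding gene, Acoxl. Erythroid and megakaryocyte genes had 4 against 2.19, with 2 in Vwf and 1 each in Lmna and at the upper end of Nfe2 (0.019 kb). Cell cycle genes had 3 against 3.59, with 1 inside Cdk4 (0.313 kb from an end), 1 inside Cdk6 (33.4 kb) and 1 lying 84.6 kb outside Ccnd2. The liver xenobiotic list had 2 against 3.58, in Gstt1 and in Pdxk, which encodes pyridoxal kinase. The neuronal list, fixed as one outside this tissue, had 2 against 6.63, at Grin1 and Snap25, a ratio of 0.301 (permutation adjusted p = 0.138). When a peak inside a gene was given to that gene first, the ratio was 0.538 (permutation adjusted p = 0.483).

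Peaks were clustered at some genes. There were 80 coding genes with 3 or more peaks against 29.4 expected from matched random regions, a ratio of 2.72 (one-sided permutation p = 0.0005, the smallest that 2000 draws can give). The excess was 1.48-fold for 2 or more peaks (414 genes) and 5.38-fold for 4 or more (16 genes). Against regions not matched on distance, the ratio for 3 or more was 4.88. The most was 5 peaks, at Asph, Gab2, Ifngr1, M1ap and Trib1. Of the Asph peaks, 1 lay 99.4 kb outside that gene and inside another coding gene, Clvs1. Trib1 encodes a pseudokinase that promotes degradation of C/EBP alpha (chromosome 15, 59648654 to 59657099). It had 1 peak 0.107 kb outside its lower end, 3 inside its 8.45 kb and 1 outside at 71.3 kb. Gab2, a signalling adaptor downstream of cytokine receptors, had 4 of its 5 inside the gene. M1ap had all 5 inside. Of the neighbouring peaks on the same chromosome, 121 pairs were within 5 kb, against a mean of 30.45 pairs and a maximum of 44 in 20 sets of matched random regions. No peaks overlapped.

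**Figure D3:**
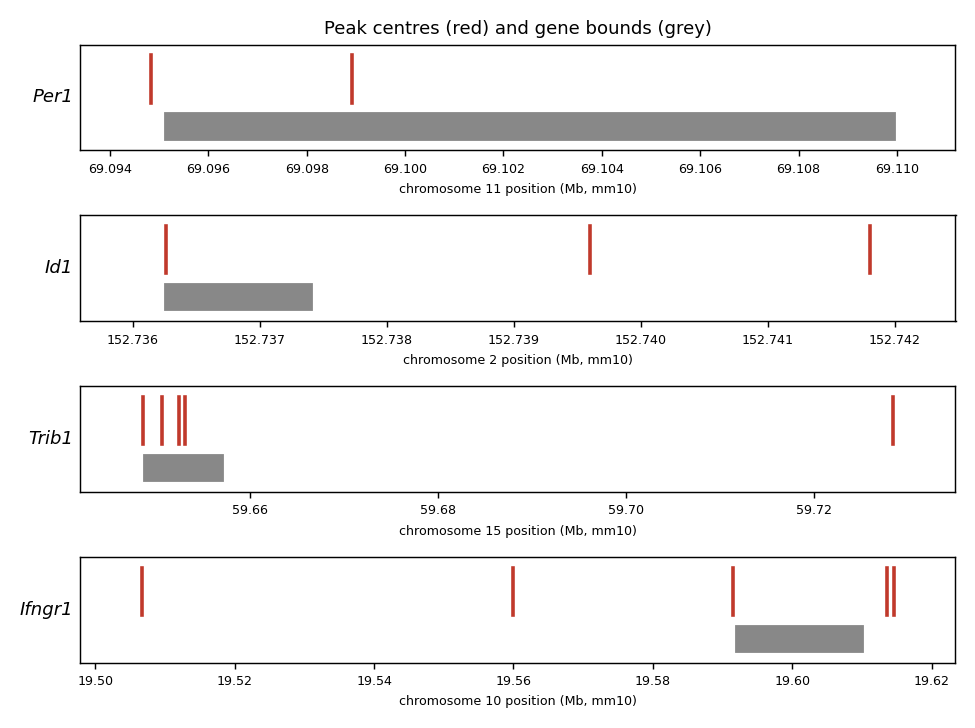
Peak centres (red) and gene bounds (grey bars) along the chromosome, in Mb of mm10, at Per1, Id1, Trib1 and Ifngr1. Per1 had 2 peaks, Id1 3, and Trib1 and Ifngr1 5 each, with 1 peak of every gene within 0.429 kb of a gene end.

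Peaks were spread over the autosomes but were sparse on X. There were 25 peaks on X, or 2.59 per 100 coding genes (95% exact interval 1.68 to 3.81), against 141 expected from its share of coding genes, a ratio of 0.178 (two-sided exact binomial adjusted p = 1.53e-32 over 20 chromosomes). By length the ratio was 0.121. Among the autosomes, chromosome 7 had the fewest with 7.68 per 100 genes (6.55 to 8.95, exact binomial adjusted p = 1.84e-19), and chromosome 15 the most with 19.8 (16.9 to 23.1, exact binomial adjusted p = 0.00122). Chromosome 7 did not stand out by length, with a ratio of 0.885 (exact binomial adjusted p = 0.186).

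**Figure D4:**
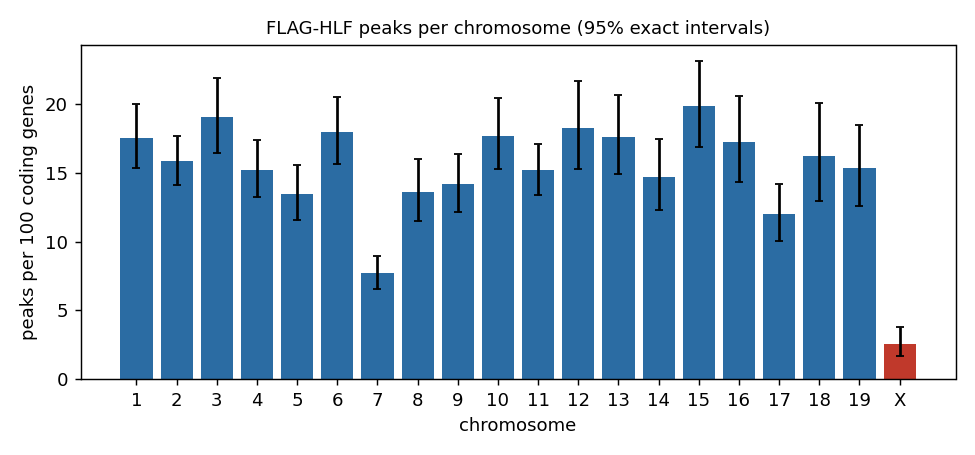
FLAG-HLF peaks per 100 coding genes on each chromosome (bars), with 95% exact intervals; X is red. X had 2.59 peaks per 100 coding genes, chromosome 7 had 7.68, and chromosome 15 had 19.8.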

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

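The test of the REST gene list along the lines of the file, and its comparison with random regions over all lines, were set down before their results were seen, but after the first 30 lines had been read and Grin1 was known to have a peak. The test within the first 315 lines, the clock-list comparison, the pooled count of the fixed lists and the tests on X were chosen after.

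The order of the lines in the peak list, which the sources used here do not explain, carried a signal. Genes of neurons were noticed at the first lines, among them Insm2 (line 1), Celsr3 (line 2), Cacng2 (line 4), Iqsec3 (line 8), Dlgap3 (line 16) and Snap25 (line 18), 4 of them with a peak within 1.06 kb of a gene end. These genes recalled targets of REST, a repressor of neuronal genes outside the nervous system. A list of 100 REST-repressed genes was therefore drawn up from general knowledge, without the neuronal genes seen in the first 30 lines. It shares 6 genes with the neuronal list. Peaks were counted here if a list gene held them, at any distance from its ends, or was nearest within 100 kb, so totals are higher for some lists than those above. Of the 33 REST-list peaks, 48.5% (16 peaks) lay in the first 315 of the 3153 lines, where 10% would lie by chance (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). They included Vgf with 2 peaks, Sst, Unc13a, Chgb, Grin1, Lhx3, Rph3a, Sez6 and Bsn. When the lines were parted into 10 blocks, the REST list held 5.06% of the peaks of the first block, 1.58% of the next, and at most 0.952% of each later one. The signal was not shown to be limited to the REST list, since the 11 fixed lists together had, by nearest gene end, 57 peaks in the first 1578 lines and 33 in the last 1575 (Fisher's exact two-sided p = 0.0135, peaks of a gene taken as independent). No single fixed list passed the one-sided permutation test of the first 315 lines after adjustment over the 11 fixed lists and the REST list. The small p of the REST list lowered the adjusted values given here. The lowest adjusted p of a fixed list was 0.0648, for the stem and multipotent progenitor list with 6 of 20 peaks in the first 315 lines. The neuronal list had 2 of 4 there (permutation adjusted p = 0.211), cytokine signalling 1 of 16 and the B lymphoid list 0 of 14.

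A chance order of the lines is argued against by that 48.5%, and an order by closeness to gene ends by the shares within 1 kb of a gene end, 10.9% in the first 1576 lines and 10.8% in the other 1577 (Fisher's exact p = 0.909). A candidate explanation is that the precipitate held sites bound by REST. The criterion set beforehand, an excess over all lines, was not met, with 29 peaks by nearest gene end against 21.7 from matched random regions, a ratio of 1.34 (two-sided permutation p = 0.15). The 15 peaks against 1.88 within the first 315 lines, a ratio of 7.96, restate the gathering already seen and decide nothing, so REST stays open. FLAG-HLF binding at the same sites stays open too, since the GFP control was not analysed here. A gathering of clock and PAR bZIP peaks in the first 315 lines, which this explanation would predict, was not seen. Of that list's peaks 15.4% (2 of 13) lay there (one-sided permutation p = 0.373 before adjustment). So few peaks cannot decide the question.

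X had 25 peaks where 141 were expected by coding genes. Fewer coding genes on X are argued against, since peaks per coding gene on chromosome 7, the lowest autosome, were 2.97 times those of X. Without olfactory and vomeronasal receptor genes the values were 9.67 per 100 genes on chromosome 7 and 2.61 on X. A single X copy per cell, which would lower the reads at each X site, could not be weighed against the ratio of 0.178, because the list gives no read counts and the labels used here give no sex. No biological explanation was tested.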

How the results depend on the processing

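Of 113 alternative values for 14 results, 98 kept their direction and their side of the threshold. The 4 lists above expectation stayed above it under every alternative run, but 2 lost the call in places. For B lymphoid genes the ratio was 1.52 with all annotated genes, 1.93 with each gene counted once and 2.61 in the first 1576 lines, none past the threshold. The last setting has fewer peaks. For the clock list it was 2.34 with each gene counted once. Against random regions not matched on distance, the stem and multipotent progenitor list (2.22) and the cell death list (3.76) passed. Without the first 315 lines the neuronal list had a ratio of 0, which is no test, since those lines were known to hold both of its counted peaks. Several lists that had not passed crossed 1, and counting any such crossing as a reversal was decided after the values were seen. The stem list was at 0.869 with all annotated genes. The T and innate lymphoid list was at 0.749 with a 20 kb limit and 0.977 without the first 315 lines. The cell cycle list was at 1.11 with no distance limit, 1.06 with all annotated genes, 1.23 against unmatched regions and 1.01 against random gene lists. The liver list was at 1.18 in the first 1576 lines. Causes were not tested. The excess at gene ends ranged from 2.36 (5 kb) to 3.62 (first 1576 lines), and X from 0.121 to 0.174. The settings on lines, the gene holding the centre, random gene lists and X were chosen after seeing the data. A stricter threshold, the stronger peaks alone, and all motif, word and peak score settings were not run, since the list gives no score and sequence was not used. The unknown depth limits every statement on genes without a peak.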

Other observations

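All tests in this part were chosen after the data were seen, except that of the Hlf gene.

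Gene families, taken as coding genes that share the letters of a symbol before its first number, were set against the same random regions. Of 153 families with at least 15 genes, from which predicted genes named Gm were left out after they had come out low, 2 had more peaks than expected and 4 had fewer at an adjusted p of 0.05. Genes of cell surface antigens named Cd had 27 peaks against 11.4, a ratio of 2.36 (permutation adjusted p = 0.0102), at 17 genes, among them Cd9 with 4 peaks, Cd34, Cd38, Cd48 and Cd69. RING finger genes named Rnf had 24 against 10.2, a ratio of 2.36 (permutation adjusted p = 0.0102). Counted once per gene, the Cd family had 17 against 10.5 (permutation p = 0.0536) and the Rnf family 17 against 9.25 (permutation p = 0.016). Olfactory receptor genes (Olfr) had 8 peaks against 65.3, and vomeronasal receptor genes (Vmn) had 0 against 35.4. Cytochrome P450 genes (Cyp) had 1 against 13.6, at Cyp7b1, and collagen genes (Col) had 0 against 10.96, each with a permutation adjusted p of 0.00765. Members of such families often lie side by side, so their peaks are not independent. The random regions were not matched on how uniquely reads can be placed there.

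Genes with 4 peaks each, chosen after their values were seen, included Lyn, a SRC family kinase of blood cells, Lcp1, which encodes the leukocyte actin-bundling protein L-plastin, Notch2, a receptor of the Notch pathway, and Ell2, an elongation factor. Lcp1 had all 4 inside the gene. Lyn had 1 inside and 3 outside, the nearest of them 12.7 kb away.

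The candidate explanation that any active gene gathers peaks was examined with housekeeping families (ribosomal, proteasome, respiratory chain and translation factor genes, 348 in all). They had 30 peaks against 28.9 expected, a ratio of 1.04 (95% exact Poisson interval 0.701 to 1.48). The ratio was 4.38 times theirs for cytokine signalling and 3.20 times theirs for granulocyte and monocyte genes (exact binomial adjusted p = 6.01e-05 and 0.00662, and 0.0234 and 0.0335 with each gene counted once). These lists were taken for their excess over random regions, and expression was not measured. The comparison therefore shows only that the housekeeping families as a set lacked such an excess, and gene activity stays open for these lists. For B lymphoid genes (2.41 times) and the clock list (2.64 times) the adjusted exact p was 0.0118 by peaks but 0.106 and 0.0571 with each gene counted once. Gene activity stays open there too. Before this test, other criteria were tried and dropped with the values in view, 1 that asked for fewer housekeeping peaks than random regions give, which the explanation does not forbid, and 1 that left out the spread of the lists. Binding at enhancers open in blood progenitors was not tested and stays open.

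There were 0 peaks within the bounds of the endogenous Hlf gene, where reads of the viral Hlf cDNA would map, and whether the authors filtered such peaks is not given in the sources used here.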
